A study of Mus musculus with 12 samples.

How the data were processed

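Total RNA from mouse liver was sequenced in 12 libraries, 1 per liver, from 5 groups: YAP controls (n = 2), YAP induced for 2 weeks (n = 2), YAP induced for 4 weeks (n = 3), MYC livers (n = 3) and MYC controls (n = 2). Per the labels, RNA was extracted with TRIzol and RNeasy columns with DNase treatment, and libraries were made with the Nugen Ovation Mouse RNA-seq kit. The authors name Trim Galore 0.4.1, HISAT2 2.1.0, featureCounts 1.6.3, DESeq2 1.20.0 and the genome build GRCm38 (mm10), without saying which step made the deposited values. The annotation release, the strand setting and the treatment of reads that map to several places are not stated. The deposited values are raw read counts per gene symbol: they are whole numbers, and each library was used as given, with none pooled.

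Each table listed 48576 genes. Of these symbols, 46271 (95.3%) matched 1 gene of GENCODE vM21 on GRCm38, which gave the coordinates. The matched symbols held at least 97.6% of the counts of each library. Cyr61 is listed under its older symbol and has no coordinates there. 27 symbols had been turned into dates by spreadsheet software, with at most 0.159% of a library's counts, and were left as they are. 2 symbols occurred on 4 lines and were not summed. Totals lay between 12511170 and 17690798 counts per library. In the 9 pairs of libraries within a group, chi-square per degree of freedom lay between 12.3 and 121, where counting error alone gives a value near 1, so replicates differed by more than counting error. Floors of 3 counts per library, used for folds against a group without counts, cover counting error only.

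Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (17964 genes), scaled by TMM, and fitted with a quasi-likelihood model with 1 mean per group over all 12 libraries, with robust dispersion estimates. The residual degrees of freedom were 7 and the common biological coefficient of variation was 31.5%. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. 5 contrasts were tested: each YAP time against YAP controls, MYC against MYC controls, 4 against 2 weeks of YAP, and the difference between the MYC effect and the 4-week YAP effect. 2 overlaps were planned, of MYC with 4-week YAP calls and of 2-week with 4-week YAP calls, with the number given by chance from the products of the call rates. The overlap of MYC with 2-week YAP calls was counted too (1518 genes with shared direction, 460 by chance). Since both YAP times share controls, 20 sets of unchanged groups were simulated against shared controls to give the correlation that sharing alone produces. TMM factors ran from 0.74 in both YAP controls to 1.35 in 4-week YAP replicate 3. The test holds the typical gene unchanged, and total-count scaling was computed beside it because the factors differed by group.

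41 gene lists were fixed before the data were examined, as were the contrasts, the rule for named genes and most of the other settings tried. 40 of them had at least 5 tested genes. They cover YAP/TAZ targets, ribosome biogenesis, nucleotide synthesis, DNA replication, mitosis, cholangiocyte, fetal and hepatocyte genes, coagulation, liver zonation, urea cycle, bile acids, lipid, glucose and drug metabolism, the growth hormone axis, sex-biased and sex chromosome genes, acute phase, p53 and stress responses, mitochondria and translation, and markers of other cell types. Pancreatic acinar markers had 1 tested gene and were not tested as a list. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 40 lists. The test was repeated with the correlation estimated from the data, and fry, which tests whether a list's genes move one way without comparing them with other genes, was run beside it. With an estimated correlation 0 lists passed in camera in any contrast, where the preset gave 27, 27, 26, 13 and 19 and fry 29, 27, 13, 0 and 10 for the contrasts in the order above. The calls of lists therefore rest on the preset correlation. Wherever a list passed camera, its median, mean and tested direction had the same sign. Among lists that did not pass, these differed in sign in 6, 1, 5, 11 and 4.

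Genes were named by a rule: in each of the 3 comparisons with controls, the 8 largest rises and 8 largest falls among called genes with at least 10 CPM in the higher group, whose libraries did not overlap, without gene models. In the other 2 contrasts the 5 largest each way were taken, without the overlap condition for the difference between effects. Up to 4 members of each list (3 in the other contrasts) with the smallest p, and a fixed set of known liver and pathway genes, were added. A gene named for 1 comparison may be given for others. The examples printed were picked from the genes named by this rule after the results of leaving out libraries were seen, with preference for those that kept their call, so they are steadier than the whole: of 586 calls among all genes named by the rule, 226 (38.6%) were lost without 1 library, against 30 of 123 (24.4%) among the examples. Folds against a group without counts were computed against 3 counts per library and are lower bounds. Where a list held such genes, its median is also given with them at their bound.

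Other settings chosen beforehand were RLE size factors, no filter, a filter of at least 1 CPM in at least 2 libraries, DESeq2 1.42.0, fits with 1 model's libraries, replicate numbers as blocks, and leaving out each library in turn. Where a group is left with 1 library, its spread is taken from the other groups. Total-count scaling, a term for the sex pattern and leaving out a list of 36 skeletal muscle genes were chosen after seeing the data. A library has a female pattern where Xist exceeds the summed Y-linked genes. Replicate numbers did not pair libraries: correlations of residuals between same-numbered libraries lay between -0.03 and 0.06 in the YAP model and between 0.02 and 0.08 in the MYC model.

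The procedure was tested on simulated data with the design's group sizes. Of 100 genes changed 2-fold it recovered 3, 10, 11, 10 and 2 in the 5 contrasts, and of 100 genes changed 4-fold it recovered 50, 56, 44, 61 and 39, with 2 to 7 unchanged genes called. With few genes changed, most 2-fold ones were missed. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. Reads of near-identical genes, such as the major urinary proteins and the RNase P RNA copies, cannot be assigned to 1 copy with certainty.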

Results

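RNA sequencing was done on total RNA of mouse livers from 2 genetic models of liver overgrowth, and 12 libraries were analysed. In the YAP model, mice carried YAPS127A, a mutant of the Hippo pathway effector YAP that escapes inhibitory phosphorylation, under a doxycycline-responsive promoter together with a Cre-dependent rtTA. An AAV with the hepatocyte-specific TBG promoter delivered Cre at 8 to 10 weeks of age. Doxycycline was then given for 2 weeks (n = 2 livers) or 4 weeks (n = 3), and mice of this genotype in which the transgene was not induced were the YAP controls (n = 2). In the MYC model, the liver-specific driver LAP-tTA activates TRE-MYC once doxycycline is withdrawn, here from the mothers at about embryonic day 8, and livers were taken 4 weeks after birth (n = 3). MYC controls carried LAP-tTA alone and followed the same doxycycline schedule (n = 2). The labels give the cell type as hepatocytes, whereas the extraction notes describe whole-liver RNA, so transcripts of other liver cells are part of each value. Libraries held between 12511170 and 17690798 counts. Gene list results give camera's adjusted p, then that with an estimated correlation, at which no list passed. Counts with total-count scaling (by total counts) follow where it moved a count of rising or falling genes by at least 2 genes and 1.5 times. Expression levels are mean normalised read counts (CPM, TMM-scaled) ± SD over the livers of a group, and log2 fold changes are given ± SE.

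Some library features moved with the groups. By Xist and Y-linked genes, both YAP controls, 2-week YAP replicate 1 and the 5 libraries of the MYC model had a male pattern, while 2-week YAP replicate 2 and the 3 4-week YAP libraries had a female pattern. Mitochondrially encoded genes took 19.5 ± 0.2% of counts in YAP controls (SD, n = 2), 10.2 and 13.9% in the 2-week libraries and 9.8 ± 2.0% at 4 weeks (n = 3). In the MYC model the share was 17.1 ± 3.2% with MYC (n = 3) and 15.4 ± 0.6% in its controls (n = 2). The summed CPM of 32 tested skeletal muscle genes was 1330 and 1450 in the 2-week YAP libraries, 203 and 187 in YAP controls, and between 37.7 and 102 at 4 weeks.

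**Figure D1:**
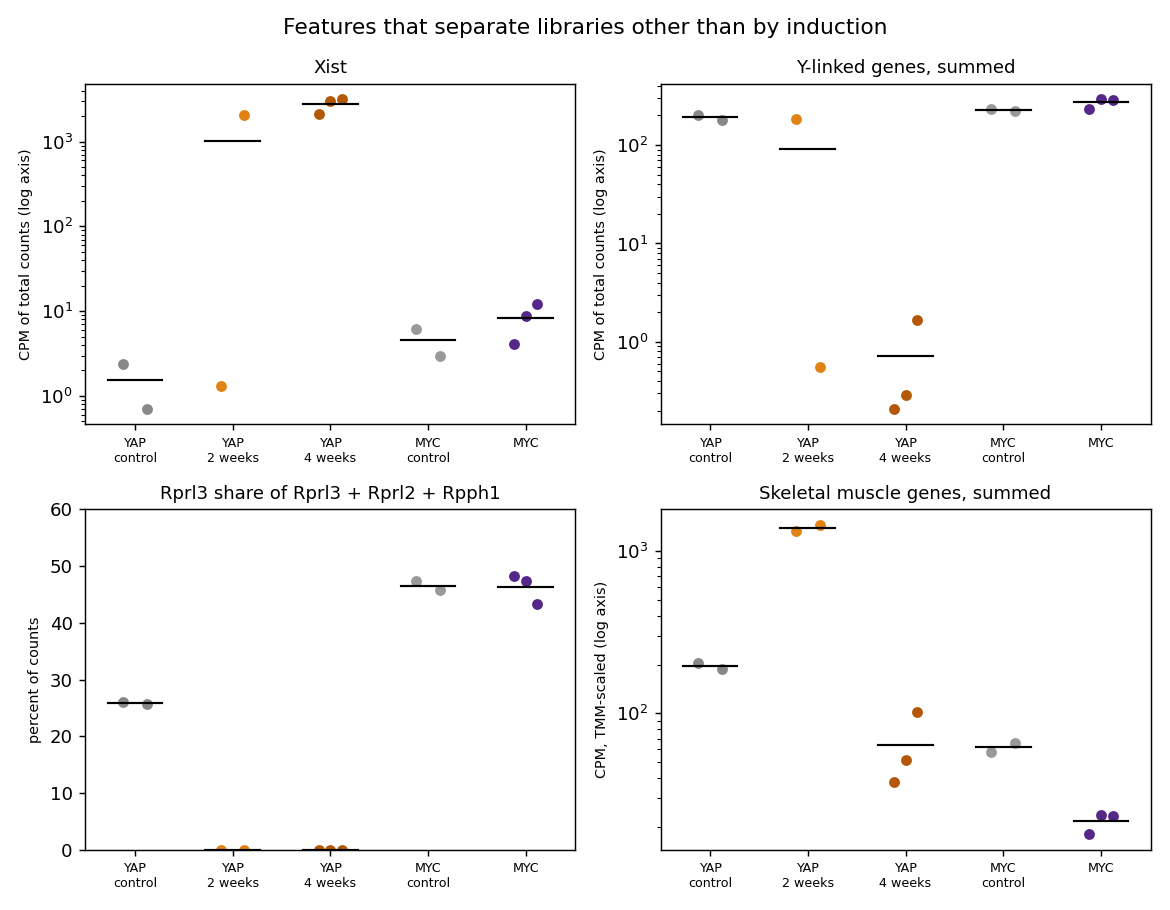
Per-library CPM of Xist, of summed Y-linked genes and of summed skeletal muscle genes (log axes), and the percent of RNase P RNA counts under the symbol Rprl3 (linear axis); each point is 1 library and each line the group mean. Xist is high in 1 of the 2 2-week and in all 3 4-week YAP libraries, muscle genes reach 1330 and 1450 CPM at 2 weeks, and the Rprl3 share is 43.3 to 48.2% in the MYC libraries and at most 0.0435% in the YAP-induced ones.

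The transgenes were looked for first under the mouse symbols. Yap1 (ENSMUSG00000053110.13, chromosome 9, 7931999 to 8004596) was at 83.8 ± 3.76 CPM in YAP controls (n = 2), 83.8 ± 5.14 CPM after 2 weeks (n = 2) and 73.4 ± 10.8 CPM after 4 weeks of induction (n = 3). Its log2 fold change at 4 weeks was -0.19 ± 0.16 (adjusted p = 0.372), whereas with scaling to total counts it was 0.54 (adjusted p = 0.0338), so its direction depended on the scaling. At 2 weeks its log2 fold change was 0 ± 0.17 (adjusted p = 1). Myc (ENSMUSG00000022346.15, chromosome 15, 61985391 to 61990374) was at 11.1 ± 6.2 CPM in MYC controls (n = 2) and 25.6 ± 5.06 CPM in MYC livers (n = 3), a log2 fold change of 1.21 ± 0.67 that did not pass (adjusted p = 0.242). The labels do not say from which species the transgenes come, and reads from a coding sequence that differs from the mouse gene need not be counted under these symbols.

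**Figure D2:**
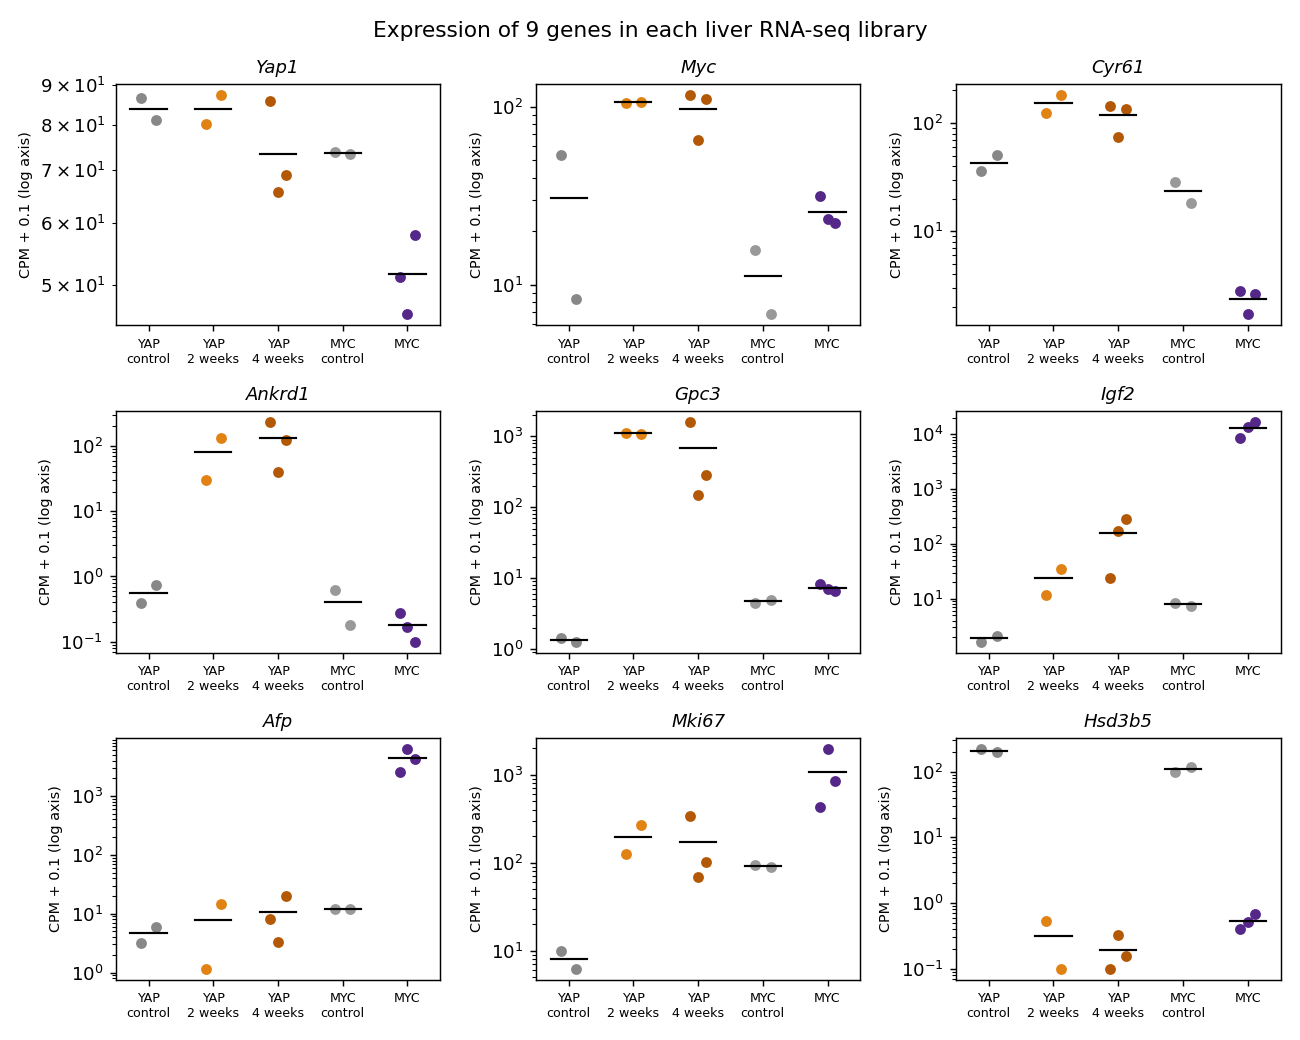
CPM plus 0.1 (log axis) of 9 genes in each library; points are libraries and lines are group means. Yap1 stays near 83.8 CPM in the control and 2-week YAP groups, Gpc3 averages 1090 CPM at 2 weeks against 1.26 in YAP controls, and Afp averages 4370 CPM in MYC livers against 11.8 in MYC controls.

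The comparison of 2 weeks of YAP induction with uninduced livers asks what the active transgene changes in the adult liver early on. Most YAP target, cell-cycle and macrophage genes tested and part of the fetal and biliary genes rose, while many genes of mature hepatocyte metabolism and of the male liver programme fell. Gpc3 (ENSMUSG00000055653.13, X chromosome, 52272426 to 52613950), a fetal liver proteoglycan, rose from 1.26 ± 0.131 to 1090 ± 30.3 CPM (SD, n = 2 per group). Glul, the glutamine synthetase of hepatocytes around the central vein, fell from 960 ± 97.2 to 80.1 ± 31.7 CPM. Of 17964 tested genes, 4993 changed, 2716 upward and 2277 downward, and 3775 of them by at least 2-fold. With total-count scaling, which shifts the median log2 fold change by 0.54, 5228 genes were higher and 979 lower.

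Among YAP/TAZ target genes, 13 of 22 rose, 1 fell and 8 did not pass (adjusted p = 8.84e-05, or 0.157 with estimated correlation), and 16 higher and 2 lower when adjusted over the list alone. Ptpn14 (chromosome 1, 189728268 to 189876695), a phosphatase that binds YAP, rose from 4.77 ± 0.458 to 61.2 ± 20.7 CPM, and Ajuba, a LIM-domain inhibitor of LATS kinases, from 5.41 ± 0.143 to 102 ± 12.4 CPM (n = 2 per group). Cyr61, a secreted matricellular protein and classical YAP target, rose from 43 ± 10.1 to 154 ± 40.5 CPM (log2 fold change 1.84 ± 0.36, adjusted p = 0.0043). Ankrd1, a muscle ankyrin repeat protein often used as a YAP readout, rose by 7.44 ± 1.25 on the log2 scale. Ctgf was at 15.8 ± 1.33 CPM in controls and 140 ± 32.3 CPM at 2 weeks without passing (adjusted p = 0.0652).

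In the mitosis list, 24 of 26 rose and 2 did not pass (adjusted p = 3.37e-10, or 0.339 with estimated correlation). Foxm1, a transcription factor of mitotic genes, rose from 1.4 ± 0.48 to 16.7 ± 6.52 CPM (n = 2 per group). Mki67, the proliferation antigen Ki-67, rose from 8.05 ± 2.69 to 196 ± 100 CPM (adjusted p = 0.00782), a call lost with adjusted p = 0.0509 and 0.0686 without YAP control replicates 1 and 2. In the DNA replication list, 20 of 28 rose, 1 fell and 7 did not pass (adjusted p = 3.94e-06, or 0.378 with estimated correlation). Lig1, the replicative DNA ligase, rose from 2.13 ± 1.64 to 31.8 ± 8.47 CPM, whereas Mcm10 was the member that fell, from 79.9 ± 2.52 to 7.62 ± 2.24 CPM. In the ribosome biogenesis list, 9 of 30 rose and 21 did not pass (adjusted p = 0.0344, or 0.489 with estimated correlation; 17 rose by total counts), a call lost with adjusted p = 0.0932 without YAP control replicate 1 and 0.093 without 2-week YAP replicate 2. Npm1, a nucleolar chaperone, rose from 145 ± 18.2 to 298 ± 26.8 CPM. Among p53 targets, 13 of 19 rose, 1 fell and 5 did not pass (adjusted p = 1.41e-05, or 0.321 with estimated correlation). Cdkn1a, the cell-cycle inhibitor p21, rose from 0.859 ± 0.0147 to 58.1 ± 14 CPM and Phlda3 from 0.661 ± 0.115 to 29.5 ± 5.14 CPM.

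Part of the biliary and fetal genes also rose. Among the cholangiocyte and progenitor markers, 8 of 21 rose and 13 did not pass (adjusted p = 0.0207, or 0.553 with estimated correlation), a call lost with adjusted p = 0.0892 without 2-week YAP replicate 2. Bicc1, an RNA-binding protein of epithelial tubes, rose from 10.3 ± 2.33 to 448 ± 29.5 CPM and Pkhd1, the polycystic kidney and liver disease protein fibrocystin, from 19.3 ± 2.95 to 139 ± 29.2 CPM (n = 2 per group). Sox9, a biliary and progenitor transcription factor, rose from 30.3 ± 0.359 to 128 ± 55.8 CPM (adjusted p = 0.017), a call lost with adjusted p = 0.0937 and 0.0969 without YAP control replicates 1 and 2 and 0.115 without 2-week YAP replicate 2. In the fetal and imprinted growth list, 10 of 19 rose, 1 fell and 8 did not pass (adjusted p = 0.000752, or 0.339 with estimated correlation), with a median log2 fold change of 3.26 (2.63 with members at 0 counts at their bound). Peg3, an imprinted zinc finger gene, rose from 5.61 ± 0.0133 to 187 ± 170 CPM, while Afp, alpha-fetoprotein, was at 4.52 ± 2.01 and 7.76 ± 9.48 CPM (adjusted p = 0.619).

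Lists of mature hepatocyte genes passed as lower, each with part of its genes. Among pericentral hepatocyte genes, 14 of 22 fell and 8 did not pass (adjusted p = 7.37e-09, or 0.339 with estimated correlation). Lgr5, a Wnt target and receptor, fell from 15.5 ± 5.7 to 0.476 ± 0.172 CPM (n = 2 per group). Among periportal genes, 10 of 22 fell and 12 did not pass (adjusted p = 2.32e-05, or 0.339 with estimated correlation). Secreted hepatocyte proteins and transcription factors moved less evenly: 7 of 25 fell and 18 did not pass (adjusted p = 0.000186, or 0.339 with estimated correlation; 2 rose and 6 fell by total counts). Ttr, transthyretin, fell from 4440 ± 136 to 821 ± 179 CPM, and Alb, albumin, was at 40400 ± 7410 and 54700 ± 8230 CPM without passing (adjusted p = 0.568). In coagulation and complement, 1 of 31 rose, 20 fell and 10 did not pass (adjusted p = 3.69e-08, or 0.339 with estimated correlation; 3 rose and 15 fell by total counts). In the urea cycle and amino acid catabolism, 14 of 34 fell and 20 did not pass (adjusted p = 1.15e-08, or 0.339 with estimated correlation). Otc, the urea cycle enzyme ornithine transcarbamylase, fell from 477 ± 49.1 to 59.6 ± 38.7 CPM. In bile acid synthesis and transport, 2 of 24 rose, 11 fell and 11 did not pass (adjusted p = 0.000665, or 0.356 with estimated correlation). Abcb11, the bile salt export pump, fell from 747 ± 14 to 70.5 ± 34 CPM while the basolateral exporter Abcc4 rose from 4.68 ± 0.764 to 23.4 ± 10.7 CPM.

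Lipid, mitochondrial and secretory pathway lists passed as lower as well, with genes that did not pass in each. In cholesterol synthesis, 16 of 25 fell and 9 did not pass (adjusted p = 1.5e-10, or 0.321 with estimated correlation). Cyp51, lanosterol demethylase, fell from 389 ± 93.5 to 51.2 ± 8.95 CPM (n = 2 per group). In fatty acid synthesis, 12 of 22 fell and 10 did not pass (adjusted p = 9.25e-07, or 0.321 with estimated correlation). In fatty acid oxidation, 6 of 30 rose, 18 fell and 6 did not pass (adjusted p = 0.000412, or 0.378 with estimated correlation; 6 rose and 10 fell by total counts). Among nuclear oxidative phosphorylation genes, 27 of 29 fell and 2 did not pass (adjusted p = 3.52e-12, or 0.321 with estimated correlation; 9 fell by total counts), with a median log2 fold change of -0.96, or -0.44 with that scaling. In mitochondrial translation and import, 12 of 28 fell and 16 did not pass (adjusted p = 1.63e-06, or 0.321 with estimated correlation; 2 rose and 6 fell by total counts), with a median of -0.61, or -0.09 with that scaling. For endoplasmic reticulum chaperones among the unfolded protein response, 17 of 22 fell and 5 did not pass (adjusted p = 4.57e-11, or 0.157 with estimated correlation). In cytosolic translation, 2 of 29 rose, 7 fell and 20 did not pass (adjusted p = 0.00775, or 0.339 with estimated correlation; 5 rose and 1 fell by total counts), with a median log2 fold change of -0.24 that became 0.3 with total-count scaling. In the integrated stress response, 9 of 23 rose and 14 did not pass (adjusted p = 0.0237, or 0.321 with estimated correlation).

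Among monocyte and recruited macrophage markers, 12 of 16 rose and 4 did not pass (adjusted p = 1.2e-06, or 0.157 with estimated correlation). Lyz2, macrophage lysozyme, rose from 31.3 ± 7.87 to 183 ± 7.51 CPM and Itgam, the integrin CD11b, from 3.9 ± 1.69 to 37.1 ± 2.61 CPM (n = 2 per group). Among Kupffer cell markers, 7 of 14 rose and 7 did not pass (adjusted p = 6.67e-05, or 0.378 with estimated correlation; 12 rose by total counts). Csf1r, the receptor of the macrophage growth factor CSF1, rose from 55.5 ± 3.56 to 465 ± 55.2 CPM. Among neutrophil markers, 8 of 13 rose and 5 did not pass (adjusted p = 0.000202, or 0.378 with estimated correlation), with a median log2 fold change of 5.27 (4.03 with members at 0 counts at their bound). Among T and NK cell markers, 3 of 14 rose and 11 did not pass (adjusted p = 0.0486, or 0.439 with estimated correlation; 5 rose by total counts), a call lost with adjusted p = 0.123 without YAP control replicate 1 and 0.0687 without 2-week YAP replicate 1. Cd3g, a T cell receptor subunit, had no counts in controls and 0.607 ± 0.157 CPM at 2 weeks, at least 2-fold higher. B cell (adjusted p = 0.0825), stellate cell (0.471), sinusoidal endothelial (0.709), erythroid (0.657), mesothelial (0.892) and adipocyte (0.892) lists did not pass. Pancreatic acinar markers were not testable as a list, with 1 tested member, Cela1, at 19.8 ± 6.06 CPM in controls and 1.19 ± 0.775 CPM at 2 weeks.

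Among male-biased liver genes, 15 of 17 fell and 2 did not pass (adjusted p = 3.52e-12, or 0.157 with estimated correlation), and 17 lower when adjusted over the list alone. Hsd3b5 (chromosome 3, 98618634 to 98630252), a steroid-metabolising enzyme of male liver, fell from 209 ± 17.7 to 0.213 ± 0.301 CPM, and Elovl3, a fatty acid elongase, from 81.3 ± 8.29 to 0.106 ± 0.15 CPM (n = 2 per group). 1 of the 2 2-week libraries had the female pattern, the other and both controls the male one. The female-biased list did not pass (adjusted p = 0.283, median log2 fold change 1.94 (0.88 with members at 0 counts at their bound)), although Cux2, a transcription factor of female liver, rose from 0.58 ± 0.82 to 72.5 ± 6.94 CPM. Among acute phase proteins, 17 of 25 fell and 8 did not pass (adjusted p = 9.57e-06, or 0.339 with estimated correlation; 2 rose and 10 fell by total counts). Saa1, serum amyloid A, fell from 4210 ± 1150 to 6.35 ± 8.05 CPM (adjusted p = 0.0102), a call lost with adjusted p = 0.0651 without 2-week YAP replicate 2, and the uninduced YAP controls stood above the MYC controls (54.9 ± 23.8 CPM, n = 2). The lists for sex chromosome genes (adjusted p = 0.217), nucleotide synthesis (0.892), glycolysis (0.919), gluconeogenesis (0.0557), xenobiotic metabolism (0.135) and the growth hormone axis (0.164) did not pass.

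The largest rises at 2 weeks that met the naming rule were mostly skeletal muscle genes, among them Myh1, Myh2, Tnnt3, Atp2a1, Xirp2 and Myh4, with Psca, a surface antigen of epithelia, beside them. Myh2, a fast muscle myosin, had no counts in controls and 81.8 ± 1.59 CPM at 2 weeks (n = 2 per group), at least 269-fold higher, and Atp2a1, the calcium pump of fast muscle, was at least 137-fold higher. Myh1 was at least 433-fold higher, Tnnt3 237-fold, Xirp2 115-fold and Myh4 112-fold on the same scale. The call of Myh1 was lost with adjusted p = 0.0605 and 0.0586 without YAP control replicates 1 and 2 and 0.0709 without 2-week YAP replicate 2. That of Xirp2 was lost with adjusted p = 0.0728 and 0.07 without YAP control replicates 1 and 2 and 0.0516 and 0.0689 without 2-week YAP replicates 1 and 2. Psca, at 0.0483 ± 0.0683 and 162 ± 44.7 CPM, lost its call with adjusted p = 0.0552 and 0.0577 without YAP control replicates 1 and 2. The largest falls included Rprl3, Mup16, Sult5a1 and Trhde. Rprl3, a gene copy of the RNase P RNA (chromosome 8, 3803069 to 3803358), fell from 498 ± 65.1 to 0.166 ± 0.0657 CPM, and Mup16, a major urinary protein gene, from 162 ± 31.7 to 0.0708 ± 0.1 CPM, where reads cannot be assigned to 1 copy with certainty. Sult5a1, a sulfotransferase, had 18.7 ± 5.53 CPM in controls and no counts at 2 weeks, at least 95.4-fold lower, and Trhde, a peptidase that degrades thyrotropin-releasing hormone, was at least 74.3-fold lower.

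The count of 4993 genes rested on few livers: it was 2716 without YAP control replicate 1, 2781 without YAP control replicate 2 and 2445 without 2-week YAP replicate 2. A term for the sex pattern, which within the YAP model can be estimated only from the difference between the 2-week libraries, gave 2565 genes.

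The comparison after 4 weeks asks what longer induction adds against the uninduced livers. Most YAP target, mitotic, biliary, fetal and myeloid genes tested were higher and many genes of hepatocyte metabolism lower. Sox9 stood at 196 ± 103 CPM (SD, n = 3) against 30.3 ± 0.359 CPM in controls (n = 2), and Spp1, osteopontin, at 1920 ± 1400 against 69.3 ± 6.51 CPM, both rises that passed (adjusted p = 0.00384 and 0.00318). Hsd3b5 fell from 209 ± 17.7 to 0.095 ± 0.12 CPM. In all, 6073 of 17964 genes changed, 3253 upward and 2820 downward, 4336 of them by at least 2-fold. With total-count scaling, a median shift of 0.73 on the log2 scale, 7863 genes were higher and 897 lower. All 3 4-week libraries had the female pattern and both controls the male pattern.

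Among YAP/TAZ targets, 14 of 22 rose and 8 did not pass (adjusted p = 0.000106, or 0.147 with estimated correlation), and 16 higher and 1 lower when adjusted over the list alone. Ptpn14 was at 90.1 ± 16 CPM and Tgfb2, a transforming growth factor, rose from 1.82 ± 0.0228 to 38.4 ± 14.4 CPM (n = 2 and 3). Ankrd1 rose from 0.463 ± 0.245 to 134 ± 98 CPM. Cyr61 rose to 118 ± 38.4 CPM (adjusted p = 0.00816) and Ctgf, connective tissue growth factor, to 167 ± 215 CPM (adjusted p = 0.0394). The Cyr61 call was lost with adjusted p = 0.0811 without YAP control replicate 1, and the Ctgf call with adjusted p = 0.175 and 0.163 without YAP control replicates 1 and 2 and 0.0632 without 4-week YAP replicate 1. In the mitosis list, 24 of 26 rose and 2 did not pass (adjusted p = 6.44e-09, or 0.372 with estimated correlation). In DNA replication, 15 of 28 rose, 1 fell and 12 did not pass (adjusted p = 0.00078, or 0.541 with estimated correlation; 23 rose and 1 fell by total counts). Foxm1 was at 14.6 ± 8.31 CPM. Among p53 targets, 10 of 19 rose, 2 fell and 7 did not pass (adjusted p = 0.00078, or 0.277 with estimated correlation; 17 rose by total counts), with Cdkn1a at 47.7 ± 9.97 CPM. Ribosome biogenesis (adjusted p = 0.44), nucleotide synthesis (0.393), the integrated stress response (0.141) and glycolysis (0.252) did not pass.

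Among cholangiocyte and progenitor markers, 12 of 21 rose and 9 did not pass (adjusted p = 0.000106, or 0.372 with estimated correlation), with a median log2 fold change of 2.7 (2.59 with members at 0 counts at their bound). Bicc1 was at 455 ± 89.1 CPM, Pkhd1 at 216 ± 84.7 CPM, and Sox4, a transcription factor of progenitors, rose from 1.71 ± 0.173 to 108 ± 62 CPM (n = 2 and 3). In the fetal list, 13 of 19 rose, 1 fell and 5 did not pass (adjusted p = 9.91e-05, or 0.277 with estimated correlation), with a median log2 fold change of 3.47 (2 with members at 0 counts at their bound). H19, an imprinted long noncoding RNA, rose from 2.09 ± 0.639 to 425 ± 342 CPM and Igf2, the neighbouring growth factor gene, from 1.78 ± 0.332 to 160 ± 131 CPM, whereas Afp did not pass (10.5 ± 8.64 CPM, adjusted p = 0.375). Gpc3 averaged 679 ± 805 CPM with a wide spread: it was 1600 CPM in replicate 1, 147 in replicate 2 and 284 in replicate 3.

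Every tested male-biased liver gene fell: 17 of 17 fell (adjusted p = 1.21e-14, or 0.147 with estimated correlation). Among female-biased genes, 8 of 19 rose, 1 fell and 10 did not pass (adjusted p = 0.0296, or 0.49 with estimated correlation), a call lost with adjusted p = 0.105 without 4-week YAP replicate 2. Their median log2 fold change was 3.87 (2.91 with members at 0 counts at their bound). Among sex chromosome genes, 1 of 6 rose, 4 fell and 1 did not pass and the list did not pass (adjusted p = 0.107). Ghr, the growth hormone receptor, fell (log2 fold change -2.76 ± 0.31), while the growth hormone and IGF list as such did not pass (adjusted p = 0.172).

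Hepatocyte lists passed as lower at 4 weeks. Among nuclear oxidative phosphorylation genes, 29 of 29 fell (adjusted p = 9.77e-15, or 0.277 with estimated correlation; 12 fell by total counts). Cycs, cytochrome c, fell from 102 ± 6.45 to 30.4 ± 7.97 CPM (n = 2 and 3). In cholesterol synthesis, 21 of 25 fell and 4 did not pass (adjusted p = 7.28e-12, or 0.277 with estimated correlation; 1 rose and 12 fell by total counts). In fatty acid synthesis, 14 of 22 fell and 8 did not pass (adjusted p = 2.62e-06, or 0.277 with estimated correlation; 6 fell by total counts). In fatty acid oxidation, 6 of 30 rose, 18 fell and 6 did not pass (adjusted p = 0.000331, or 0.384 with estimated correlation; 6 rose and 8 fell by total counts). In the urea cycle and amino acid catabolism, 25 of 34 fell and 9 did not pass (adjusted p = 1.93e-11, or 0.277 with estimated correlation; 15 fell by total counts). Cps1, the first enzyme of the cycle, fell from 5100 ± 582 to 1710 ± 145 CPM (adjusted p = 0.00376). In coagulation and complement, 25 of 31 fell and 6 did not pass (adjusted p = 2.25e-10, or 0.277 with estimated correlation; 3 rose and 14 fell by total counts). In acute phase proteins, 15 of 25 fell and 10 did not pass (adjusted p = 2.62e-06, or 0.31 with estimated correlation; 2 rose and 9 fell by total counts). Among endoplasmic reticulum chaperones, 18 of 22 fell and 4 did not pass (adjusted p = 2.49e-11, or 0.147 with estimated correlation; 1 rose and 11 fell by total counts). Among pericentral genes, 15 of 22 fell and 7 did not pass (adjusted p = 5.97e-09, or 0.294 with estimated correlation). Glul was at 52.2 ± 17.3 CPM. Among periportal genes, 12 of 22 fell and 10 did not pass (adjusted p = 3.09e-06, or 0.31 with estimated correlation; 2 rose and 8 fell by total counts).

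Further lists passed as lower with part of their genes. Among secreted proteins and transcription factors, 13 of 25 fell and 12 did not pass (adjusted p = 3.28e-05, or 0.277 with estimated correlation; 3 rose and 5 fell by total counts), with a median of -0.8, or -0.07 with that scaling. In bile acid synthesis and transport, 2 of 24 rose, 14 fell and 8 did not pass (adjusted p = 0.000214, or 0.31 with estimated correlation; 4 rose and 10 fell by total counts). In xenobiotic metabolism, 1 of 30 rose, 3 fell and 26 did not pass (adjusted p = 0.0123, or 0.552 with estimated correlation; 4 rose and 3 fell by total counts), with a median of -0.76, or -0.02 with that scaling. In gluconeogenesis and glycogen, 5 of 17 fell and 12 did not pass (adjusted p = 0.00748, or 0.392 with estimated correlation; 5 rose and 4 fell by total counts), and the median log2 fold change of -0.47 became 0.23 with total-count scaling. Mitochondrial translation passed as lower with 16 genes that fell (adjusted p = 9.98e-09, or 0.277 with estimated correlation; 3 rose and 4 fell by total counts). Cytosolic translation did with 10 (adjusted p = 0.000534, or 0.277 with estimated correlation; 9 rose and 1 fell by total counts). Their medians of -0.71 and -0.32 became 0.02 and 0.41 with total-count scaling.

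Among monocyte and recruited macrophage markers, 14 of 16 rose and 2 did not pass (adjusted p = 3.09e-06, or 0.147 with estimated correlation), with Lyz2 at 128 ± 4.49 CPM and Cx3cr1, a chemokine receptor, rising from 1.02 ± 0.21 to 24.7 ± 6.06 CPM (n = 2 and 3). Among neutrophil markers, 10 of 13 rose and 3 did not pass (adjusted p = 6.34e-05, or 0.372 with estimated correlation), with a median log2 fold change of 5.57 (3.88 with members at 0 counts at their bound). The Kupffer list did not pass (adjusted p = 0.437), although Csf1r rose to 238 ± 105 CPM. Sinusoidal endothelial markers passed as lower, where 4 of 19 fell and 15 did not pass (adjusted p = 0.0185, or 0.594 with estimated correlation; 4 rose by total counts), a call lost with adjusted p = 0.2 without 4-week YAP replicate 3. The median log2 fold change of -0.35 became 0.37 with total-count scaling. T and NK cell (adjusted p = 0.337), B cell (0.338), stellate (0.704), erythroid (0.66), mesothelial (0.262) and adipocyte (0.477) lists did not pass.

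The largest rises at 4 weeks included Zfp185, a LIM-domain protein, from no counts in controls to 22.2 ± 11.4 CPM (n = 2 and 3), at least 73.1-fold, and Sdk1, a cell adhesion protein, to 14.2 ± 1.39 CPM, at least 46.6-fold. The largest falls were in the major urinary protein family and Elovl3: Mup7 went from 1660 ± 99.4 to 0.315 ± 0.274 CPM and Mup17 from 1190 ± 325 to 0.318 ± 0.277 CPM. The count of 6073 genes was 3340 without YAP control replicate 1 and 3324 without YAP control replicate 2. With a sex term, estimated from the 2-week libraries alone, 240 genes passed, and with replicate numbers as blocks 3539 did.

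The direct comparison of 4 with 2 weeks asks what changes with longer induction. At the level of single genes, 11 passed and all 11 were lower at 4 weeks, most of them genes of striated muscle: Atp2a1, Cmya5, Des, Mybpc1, Myh4, Myom1, Neb, Ryr1, Tpm2 and Ttn, and the gene model Gm10499. Ttn, the giant sarcomere protein titin (chromosome 2, 76703980 to 76982547), fell from 510 ± 26.3 CPM (n = 2) to 15.7 ± 15.4 CPM (n = 3), with 1.47 ± 0.0254 CPM in controls. Of the 11 calls, 0 were kept in edgeR without 2-week YAP replicate 1, where 801 genes in all had an unadjusted p under 0.05, and 4 without 2-week YAP replicate 2. 1 was kept without 4-week YAP replicate 2, 6 without 4-week YAP replicate 3, and all 11 without 4-week YAP replicate 1 and with DESeq2. For Ttn this gave adjusted p = 0.214 and 0.161 without 2-week YAP replicates 1 and 2 and 0.0951 without 4-week YAP replicate 2. Genes of the 11 outside the naming rule are named because the count is small. Kupffer cell markers were lower as a list, with a median log2 fold change of -1.39 (adjusted p = 1.95e-14, or 0.635 with estimated correlation), although 0 of 14 passed singly in edgeR, where 11 had an unadjusted p under 0.05 and DESeq2 called 1. Csf1r was at 465 ± 55.2 CPM at 2 and 238 ± 105 CPM at 4 weeks (adjusted p = 0.505). Sinusoidal endothelial markers (adjusted p = 5.84e-09, or 0.635 with estimated correlation) and p53 targets (adjusted p = 0.000332, or 0.635 with estimated correlation) also passed as lower.

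Further lists passed as lower at 4 weeks. DNA replication genes had a median log2 fold change of -0.53 (adjusted p = 0.000127, or 0.735 with estimated correlation), a call lost with adjusted p = 0.0548 without 4-week YAP replicate 2. Ribosome biogenesis had -0.21 (adjusted p = 0.0016, or 0.635 with estimated correlation), lost with adjusted p = 0.13 without 2-week YAP replicate 2. Glycolysis had -0.23 (adjusted p = 0.00557, or 0.635 with estimated correlation), lost with adjusted p = 0.13 without 2-week YAP replicate 2. Oxidative phosphorylation had -0.17, which became 0.02 with total-count scaling (adjusted p = 0.00262, or 0.735 with estimated correlation), and the call was lost with adjusted p = 0.456 without 2-week YAP replicate 1. Mitochondrial translation had -0.13, or 0.07 with total-count scaling (adjusted p = 0.0497, or 0.735 with estimated correlation), lost with adjusted p = 0.318 without 2-week YAP replicate 1 and 0.0789, 0.052 and 0.13 without 4-week YAP replicates 1, 2 and 3. The urea cycle had -0.25 (adjusted p = 0.0181, or 0.79 with estimated correlation), lost with adjusted p = 0.318 without 2-week YAP replicate 1 and 0.0813 and 0.0523 without 4-week YAP replicates 1 and 3. Its direction turned without 2-week YAP replicate 1. Male-biased genes had -1.83 (adjusted p = 0.000197, or 0.635 with estimated correlation), lost with adjusted p = 0.939 without 2-week YAP replicate 1, the library with the male pattern. Of each of these lists, 0 genes passed over all genes tested with edgeR, where 1250 of 17964 genes had an unadjusted p under 0.05 and DESeq2 called 77 genes in all.

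Lists passed as higher at 4 weeks for cholangiocyte and progenitor markers, female-biased genes and mesothelial markers. Cholangiocyte and progenitor markers had a median log2 fold change of 1.13 (adjusted p = 9.2e-05, or 0.635 with estimated correlation), lost with adjusted p = 0.101 without 2-week YAP replicate 1. Epcam, an epithelial adhesion molecule, was at 5.04 ± 0.191 CPM at 2 weeks (n = 2) and 21.5 ± 17.8 CPM at 4 weeks (n = 3). Female-biased genes had 1.21 (adjusted p = 0.00518, or 0.635 with estimated correlation), beside 1 of 2 libraries with the female pattern at 2 weeks and 3 of 3 at 4 weeks. Mesothelial markers had 0.96 (adjusted p = 0.00518, or 0.635 with estimated correlation), lost with adjusted p = 0.0545 without 4-week YAP replicate 2. Stellate cell markers (adjusted p = 0.731) and neutrophil markers (0.356) did not pass and turned direction without 4-week YAP replicate 1 (adjusted p = 0.0262 for stellate markers) and without 2-week YAP replicate 1 (adjusted p = 0.000306 for neutrophil markers). The remaining lists did not pass. The gene count itself was 1, none of the 11, without 2-week YAP replicate 1, 501 without 4-week YAP replicate 1 and 1 without 4-week YAP replicate 2. It was 5 without the skeletal muscle list, 4 of them the muscle genes Cmya5, Des, Myom1 and Tpm2 outside it, 3 with total-count scaling and 0 with a sex term.

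The calls at 2 and 4 weeks overlapped. 2242 genes rose and 1996 fell at both times, where chance gives 492 and 357, and 2 moved in opposite directions. Log2 fold changes across genes had correlations of 0.9 (Pearson) and 0.89 (Spearman), in which genes are not independent replicates. Both times share their control livers. Unchanged groups simulated against shared controls gave a mean Pearson correlation of 0.588 and a covariance of 0.209 (3.63 in the data). They had 0 calls at 4 weeks, so cannot test shared calls. The number of genes with shared direction, 4238, was 2283 without YAP control replicate 1, 2349 without YAP control replicate 2, 2207 without 2-week YAP replicate 2 and 237 with a sex term.

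The MYC comparison asks what MYC expression from embryonic life onward changes in the liver 4 weeks after birth. Most fetal growth, erythroid, neutrophil and DNA replication genes tested rose, while most lipid synthesis and male-biased genes fell. H19 rose from 12.2 ± 1.38 CPM (n = 2) to 20700 ± 6060 CPM (SD, n = 3), and Igf2 from 7.82 ± 0.692 to 13000 ± 4230 CPM. Igf1, the growth-hormone-dependent insulin-like growth factor of the postnatal liver, fell from 1740 ± 179 to 377 ± 118 CPM. Of 17964 genes, 3291 changed, 1754 upward and 1537 downward, and 2371 by at least 2-fold. With total-count scaling, a median shift of 0.41, 3277 were higher and 743 lower. All 5 libraries had the male pattern.

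In the fetal and imprinted growth list, 12 of 19 rose, 1 fell and 6 did not pass (adjusted p = 2.05e-08, or 0.34 with estimated correlation), and 13 higher and 1 lower when adjusted over the list alone. H19 and Igf2 lie next to each other on chromosome 7, H19 at 142575529 to 142578143 and Igf2 at 142650766 to 142666816. Meg3, a maternally expressed noncoding RNA on chromosome 12, rose from 1.34 ± 0.235 to 153 ± 66.9 CPM, and Cdkn1c, an imprinted cell-cycle inhibitor, from 1.68 ± 0.5 to 82.2 ± 44.6 CPM (n = 2 and 3). Afp rose from 11.8 ± 0.0679 to 4370 ± 1890 CPM (adjusted p = 0.00371), a call lost with adjusted p = 0.0585 and 0.0552 without MYC control replicates 1 and 2. Gpc3 was at 4.58 ± 0.356 and 7.18 ± 0.9 CPM and did not pass (adjusted p = 0.647).

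Among erythroid markers, 12 of 17 rose and 5 did not pass (adjusted p = 8.58e-09, or 0.369 with estimated correlation), with a median log2 fold change of 5.91 (6.05 with members at 0 counts at their bound). Rhag, a red cell membrane glycoprotein, went from no counts to 37.8 ± 28.1 CPM, at least 151-fold, and Klf1, the erythroid Krüppel-like factor, from 1.95 ± 0.993 to 56.5 ± 36.6 CPM (n = 2 and 3). Among neutrophil markers, 12 of 13 rose and 1 did not pass (adjusted p = 3.25e-10, or 0.369 with estimated correlation), with a median of 7.84 (7.6 with members at 0 counts at their bound). Elane, neutrophil elastase, rose from 0.0442 ± 0.0625 to 29.4 ± 10.7 CPM. Among monocyte and macrophage markers, 11 of 16 rose, 1 fell and 4 did not pass (adjusted p = 7.93e-08, or 0.228 with estimated correlation). Lyz2 rose from 21.1 ± 0.537 to 131 ± 31.2 CPM and Cx3cr1 fell from 5.06 ± 0.782 to 0.966 ± 0.518 CPM, the latter a call lost with adjusted p = 0.0722 without MYC control replicate 2. Among Kupffer markers, 4 of 14 rose and 10 did not pass (adjusted p = 0.0231, or 0.639 with estimated correlation; 6 rose by total counts), a call lost with adjusted p = 0.0582 without MYC replicate 1 and 0.0677 without MYC control replicate 2. Sinusoidal endothelial markers passed as lower, where 4 of 19 fell and 15 did not pass (adjusted p = 8.03e-05, or 0.569 with estimated correlation; 1 fell by total counts), and 10 lower when adjusted over the list alone. Stellate markers passed as lower with a median of -0.67 though 0 of 24 passed singly in edgeR, with 4 at an unadjusted p under 0.05, and 0 in DESeq2 (adjusted p = 0.0244, or 0.694 with estimated correlation), and the call was lost with adjusted p = 0.0608 without MYC replicate 2. T and NK cell (adjusted p = 0.0984), B cell (0.818), mesothelial (0.313) and adipocyte (0.801) lists did not pass.

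In DNA replication, 18 of 28 rose, 2 fell and 8 did not pass (adjusted p = 5.83e-08, or 0.569 with estimated correlation), and 22 higher and 2 lower when adjusted over the list alone. Mcm6, a subunit of the replicative helicase, rose from 11.6 ± 6.82 to 64.6 ± 36.4 CPM (n = 2 and 3), a call lost with adjusted p = 0.0948 without MYC control replicate 1. In mitosis, 8 of 26 rose and 18 did not pass (adjusted p = 4.62e-07, or 0.569 with estimated correlation; 19 rose by total counts), and 19 higher when adjusted over the list alone. Mki67 rose from 91.7 ± 4.55 to 1080 ± 796 CPM (adjusted p = 0.0228), a call lost with adjusted p = 0.0545 without MYC replicate 2 and 0.16 and 0.155 without MYC control replicates 1 and 2. In ribosome biogenesis, 6 of 30 rose and 24 did not pass (adjusted p = 0.0176, or 0.569 with estimated correlation; 13 rose by total counts), a call lost with adjusted p = 0.121 without MYC replicate 1 and 0.0655 without MYC control replicate 1. Npm1 rose from 140 ± 5.9 to 306 ± 43 CPM. Nucleotide synthesis did not pass as a list (adjusted p = 0.196). Ncl, Cad and Odc1, known MYC targets for nucleolin, pyrimidine synthesis and polyamine synthesis, were at 594 ± 70, 63.6 ± 4.79 and 68.7 ± 29.4 CPM against 410 ± 4.85, 36.5 ± 0.0529 and 32.1 ± 4.48 CPM without passing (adjusted p = 0.0556, 0.109 and 0.284). The integrated stress response (adjusted p = 0.586), where 6 of 23 rose, 5 fell and 12 did not pass, or 8 rose and 4 fell with total-count scaling, and p53 targets (0.996), where 2 of 19 rose, 2 fell and 15 did not pass, or 5 rose and 1 fell, went both ways and did not pass as lists. Asns, asparagine synthetase, rose from 5.43 ± 2.68 to 71.1 ± 21.1 CPM and Cdkn1a from 9.58 ± 3.07 to 40.1 ± 13.7 CPM.

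In fatty acid synthesis, 16 of 22 fell and 6 did not pass (adjusted p = 8.8e-09, or 0.34 with estimated correlation; 10 fell by total counts). In cholesterol synthesis, 15 of 25 fell and 10 did not pass (adjusted p = 9.87e-09, or 0.369 with estimated correlation). Among male-biased genes, 1 of 17 rose, 14 fell and 2 did not pass (adjusted p = 2.1e-09, or 0.34 with estimated correlation). Hsd3b5 fell from 109 ± 14.1 to 0.433 ± 0.142 CPM (n = 2 and 3). The member that rose was Cyp4a12b, a fatty acid hydroxylase, from 4.96 ± 0.615 to 41.7 ± 14.6 CPM, a call lost with adjusted p = 0.0601 and 0.0682 without MYC control replicates 1 and 2. Among female-biased genes, 6 of 19 rose and 13 did not pass (adjusted p = 0.0181, or 0.569 with estimated correlation), a call lost with adjusted p = 0.224 without MYC replicate 1. In the growth hormone and IGF axis, 1 of 17 rose, 5 fell and 11 did not pass (adjusted p = 0.0176, or 0.369 with estimated correlation), and the median log2 fold change of -0.43 became -0.01 with total-count scaling. Ghr fell from 782 ± 26.1 to 225 ± 42.3 CPM and Socs2, a growth hormone target, from 37.1 ± 0.112 to 7.05 ± 3.78 CPM. Sex chromosome genes did not pass (adjusted p = 0.95).

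Hepatocyte function lists passed as lower with part of their genes. For secreted proteins and transcription factors, 10 of 25 fell and 15 did not pass (adjusted p = 1.3e-06, or 0.369 with estimated correlation; 5 fell by total counts). Ppara, the fatty acid receptor, fell from 163 ± 0.0889 to 64.4 ± 18.1 CPM (n = 2 and 3). Alb fell from 66700 ± 1740 to 21200 ± 8800 CPM (adjusted p = 0.032), a call lost with adjusted p = 0.0927 and 0.0918 without MYC replicates 2 and 3 and 0.136 and 0.136 without MYC control replicates 1 and 2. In coagulation and complement, 10 of 31 fell and 21 did not pass (adjusted p = 1.21e-06, or 0.569 with estimated correlation; 2 rose and 5 fell by total counts). Pericentral genes (adjusted p = 7.81e-06, or 0.569 with estimated correlation; 1 rose and 3 fell by total counts) and the urea cycle (adjusted p = 2.82e-06, or 0.569 with estimated correlation) passed with 5 and 6 genes that fell. For periportal genes, 2 of 22 rose, 3 fell and 17 did not pass (adjusted p = 0.0176, or 0.569 with estimated correlation), a call lost with adjusted p = 0.0556 without MYC replicate 3. In bile acid metabolism, 2 of 24 rose, 7 fell and 15 did not pass (adjusted p = 0.00641, or 0.569 with estimated correlation; 4 rose and 5 fell by total counts).

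In xenobiotic metabolism, 1 of 30 rose, 4 fell and 25 did not pass (adjusted p = 0.0032, or 0.569 with estimated correlation). In gluconeogenesis, 1 of 17 rose, 4 fell and 12 did not pass (adjusted p = 0.0032, or 0.569 with estimated correlation; 2 rose and 2 fell by total counts). In fatty acid oxidation, 2 of 30 rose, 5 fell and 23 did not pass (adjusted p = 0.0147, or 0.569 with estimated correlation; 5 rose and 5 fell by total counts), a call lost with adjusted p = 0.102 without MYC control replicate 1. Its median of -0.53 became -0.13 with that scaling. Chaperones of the unfolded protein response (adjusted p = 0.0174, or 0.569 with estimated correlation; 2 rose by total counts) and mitochondrial translation (adjusted p = 0.0221, or 0.569 with estimated correlation; 1 rose by total counts) passed as lower with medians of -0.3 and -0.2, which became 0.11 and 0.21 with total-count scaling. The mitochondrial translation call was lost with adjusted p = 0.0611 and 0.076 without MYC replicates 2 and 3 and 0.0816 without MYC control replicate 1. YAP/TAZ targets (adjusted p = 0.207), cholangiocyte markers (0.929), acute phase proteins (0.559), oxidative phosphorylation (0.135), cytosolic translation (0.95) and glycolysis (0.207) did not pass. Among YAP/TAZ targets Axl, a receptor tyrosine kinase, rose from 21.3 ± 0.923 to 78.7 ± 14.4 CPM and Cyr61 fell from 23.4 ± 7.23 to 2.3 ± 0.604 CPM (n = 2 and 3). Yap1 itself fell from 73.5 ± 0.243 to 51.5 ± 6.07 CPM (adjusted p = 0.0419), a call lost with adjusted p = 0.0626 and 0.137 without MYC replicates 1 and 2 and 0.201 and 0.18 without MYC control replicates 1 and 2.

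The largest rises with MYC by the naming rule included Shbg, Rhag and Dlk1. Shbg, sex hormone-binding globulin (chromosome 11, 69614804 to 69617905), had no counts in controls and 43.6 ± 18.2 CPM with MYC (n = 2 and 3), at least 175-fold higher. Dlk1, an imprinted fetal growth regulator, was at least 111-fold higher, a call lost with adjusted p = 0.0621 and 0.0614 without MYC control replicates 1 and 2. The largest falls by it were mostly major urinary protein genes, with Mup5 going from 385 ± 129 to 0.058 ± 0.101 CPM and Mup9 and Mup18 at least 439-fold and 410-fold lower. The count of 3291 genes was 1683 without MYC replicate 2, 792 without MYC control replicate 1 and 872 without MYC control replicate 2. With replicate numbers as blocks it was 1514.

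**Figure D3:**
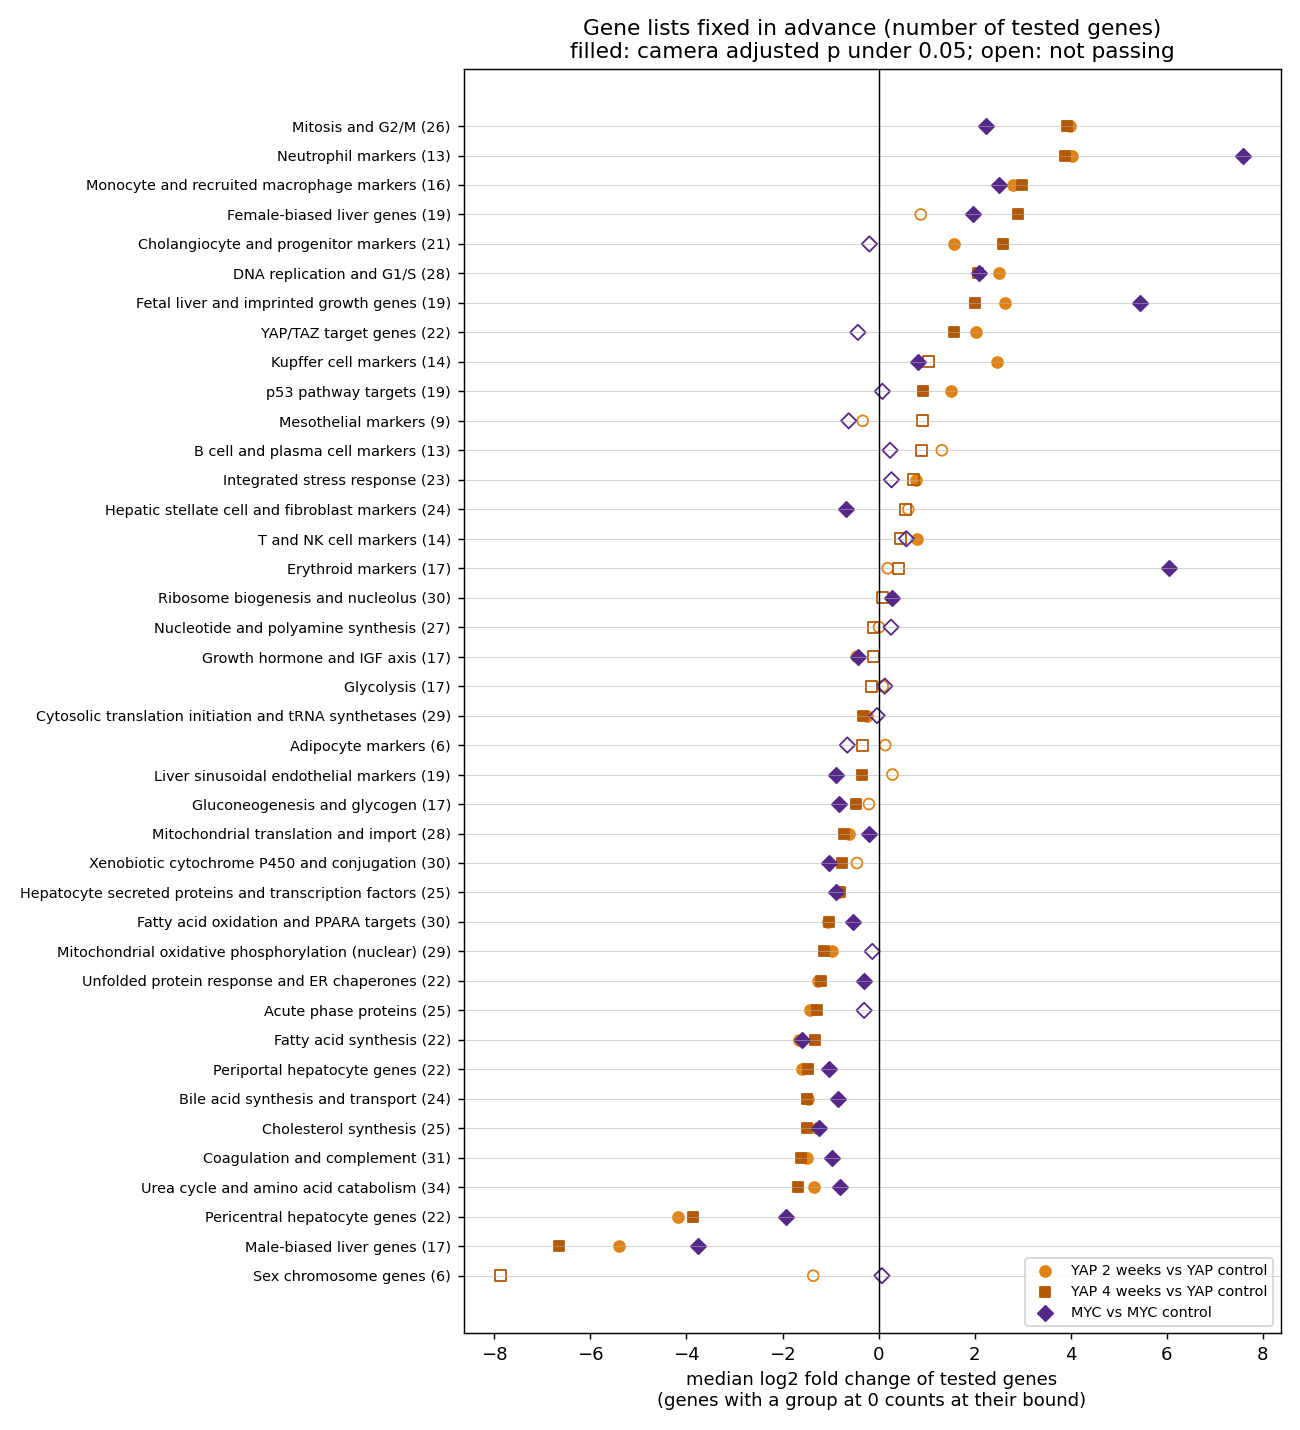
Median log2 fold change of the tested genes of each of the 40 lists, with genes at 0 counts in a group set to their bound (x axis), and list names and numbers of tested genes on the y axis; colours mark the 3 comparisons with controls, and filled symbols passed camera at an adjusted p under 0.05. Male-biased genes lie at -5.41, -6.65 and -3.76 for YAP at 2 weeks, YAP at 4 weeks and MYC, mitosis genes at 3.98, 3.92 and 2.24.

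The 2 models were compared through their overlap and through a test of the difference between their effects. 847 genes rose and 813 fell in both MYC and 4-week YAP livers, where chance gives 318 and 241, and 131 moved in opposite directions, where chance gives 554. Log2 fold changes across genes had a Pearson and a Spearman correlation of 0.45, in which genes are not independent replicates, and the models share no control livers. Elovl3 fell in both, to 0.0185 ± 0.0321 CPM with YAP (n = 3) and 0.0427 ± 0.0375 CPM with MYC (n = 3), and Bex1, a small brain-expressed protein, rose in both, to 17.7 ± 9.61 and 74.4 ± 28.6 CPM. The number with shared direction, 1660, was 985 without YAP control replicate 1, 991 without YAP control replicate 2, 948 without MYC replicate 2, 460 without MYC control replicate 1 and 531 without MYC control replicate 2. It was 2630 with total-count scaling, 117 with a sex term and 732 with replicate numbers as blocks.

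**Figure D4:**
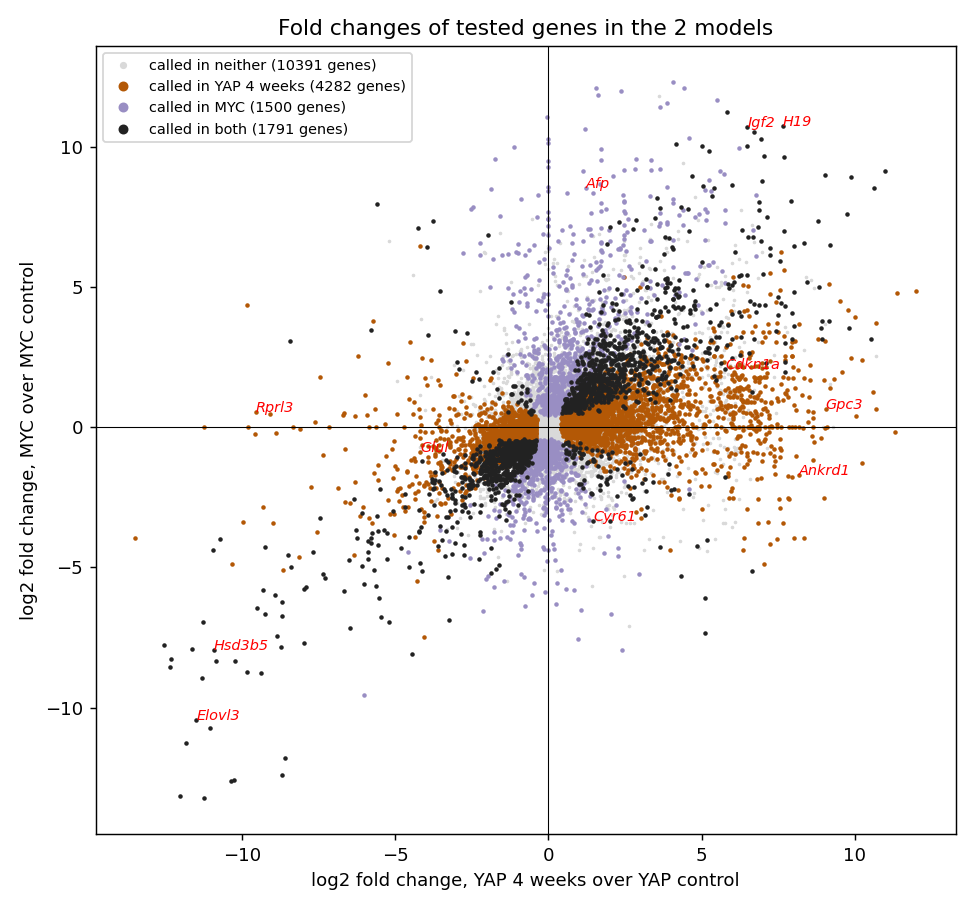
Log2 fold change with MYC (y axis) against log2 fold change after 4 weeks of YAP (x axis) for the 17964 tested genes, each a point coloured by the comparison in which it passed; fitted values at the extremes depend on the prior count. 1791 genes passed in both, and Elovl3 and Hsd3b5 lie low on both axes while Cyr61 rose with YAP and fell with MYC.

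The difference between the effects passed for 1344 genes, 566 with a higher MYC effect and 778 with a lower one. With total-count scaling, a median shift of -0.32, 270 and 1260 did. Age, doxycycline schedule, genotype and, at 4 weeks, sex pattern go together with the model. YAP/TAZ targets had a lower effect with MYC: 10 of 22 differed singly and the median difference was -2.58 (-2.7 with members at 0 counts at their bound) (adjusted p = 5.55e-07, or 0.145 with estimated correlation). Ptpn14 differed by -4.5 ± 0.38 and Cyr61 by -4.79 ± 0.5 on the log2 scale (adjusted p = 0.000289 and 0.000804). Cholangiocyte markers differed the same way, 7 of 21 being lower (adjusted p = 6.23e-05, or 0.615 with estimated correlation), and Pkhd1 by -4.06 ± 0.4. So did p53 targets, with 6 of 19 lower (adjusted p = 0.000432, or 0.461 with estimated correlation; 9 lower by total counts), and Phlda3 by -4.15 ± 0.53. The cholangiocyte median difference was -2.6 (-2.24 with members at 0 counts at their bound).

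Other lists had a higher effect with MYC. For nuclear oxidative phosphorylation, 17 of 29 genes differed (adjusted p = 2.67e-13, or 0.461 with estimated correlation; 9 higher by total counts). For chaperones of the unfolded protein response 12 of 22 did (adjusted p = 1.5e-08, or 0.461 with estimated correlation). For acute phase proteins 6 of 25 did (adjusted p = 3.69e-05, or 0.611 with estimated correlation), among them Lbp, which binds lipopolysaccharide, by 2.63 ± 0.32. For erythroid markers, 3 of 17 differed (adjusted p = 4.56e-08, or 0.461 with estimated correlation), with Klf1 by 5.81 ± 0.84. For mitochondrial translation 5 of 28 did (adjusted p = 3.69e-05, or 0.461 with estimated correlation). With total-count scaling the 5 became 0 in edgeR, with 6 at an unadjusted p under 0.05 and 7 called by DESeq2, and the median difference of 0.41 became 0.08. Male-biased genes (adjusted p = 6.23e-05, or 0.461 with estimated correlation) and cytosolic translation (adjusted p = 0.000432, or 0.461 with estimated correlation) passed as well. Neutrophil markers passed with a median difference of 1.92 (3.09 with members at 0 counts at their bound) (adjusted p = 0.00459, or 0.729 with estimated correlation), though 0 of 13 differed singly in edgeR, with 3 at an unadjusted p under 0.05, and 2 in DESeq2. The MYC effect on Glul was higher by 3.32 ± 0.43, beside pericentral genes as a list (adjusted p = 0.00343, or 0.729 with estimated correlation), a call lost with adjusted p = 0.073 without MYC replicate 1. Periportal genes passed (adjusted p = 0.00317, or 0.729 with estimated correlation), a call lost with adjusted p = 0.103 without MYC replicate 1. The urea cycle passed (adjusted p = 0.000924, or 0.729 with estimated correlation; 1 higher by total counts), lost with adjusted p = 0.0626 without MYC replicate 1. Coagulation passed with 2 genes higher and 1 lower (adjusted p = 0.00728, or 0.764 with estimated correlation; 2 higher and 3 lower by total counts), lost with adjusted p = 0.0879 without MYC replicate 1, and the median of 0.45 became 0.1 with that scaling. Cholesterol synthesis passed (adjusted p = 0.00279, or 0.729 with estimated correlation), lost with adjusted p = 0.104 without YAP control replicate 2. Glycolysis passed (adjusted p = 0.00551, or 0.461 with estimated correlation), lost with adjusted p = 0.0578 without YAP control replicate 2.

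Mitosis genes had a lower effect with MYC (adjusted p = 0.00748, or 0.813 with estimated correlation), lost with adjusted p = 0.0508 without YAP control replicate 2, 0.112 without 4-week YAP replicate 1 and 0.0879 without MYC replicate 1. Singly 0 of 26 differed in edgeR, with 4 at an unadjusted p under 0.05, and 3 in DESeq2. Stellate markers had a lower effect too (adjusted p = 0.0416, or 0.813 with estimated correlation), lost with adjusted p = 0.262 and 0.0517 without 4-week YAP replicates 2 and 3 and 0.0847 and 0.0848 without MYC replicates 2 and 3. The remaining lists did not pass. The gene count was 510 without YAP control replicate 1 or replicate 2, 808 without 4-week YAP replicate 3, 491 without MYC control replicate 1 and 338 without MYC control replicate 2. DESeq2 gave 2350 genes, replicate numbers as blocks 308 and a sex term 65.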

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

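All tests of explanations in this part were chosen after the results were seen.

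The difference between 4 and 2 weeks of YAP was tested directly and passed for 11 genes, the 6 largest falls being Myh4 (log2 difference -9.48), the gene model Gm10499 (-7.27), Atp2a1 (-5.1), Ttn (-5.02), Mybpc1 (-4.77) and Ryr1 (-4.74). Of 32 tested skeletal muscle genes, 31 were higher in both 2-week libraries than in both controls. Their median 4-week level was 3% of the 2-week level, which restates the difference and decides no explanation. Muscle tissue taken along with the liver may be a source but stays open. Ttn was at 491 and 528 CPM at 2 weeks, Acta1 at 59.1 and 83.3 and Ckm at 12.8 and 12.5. Mylpf was at 2.34 and 7.89 and Tnnc2 at 0.283 and 0.418. CPM ignores transcript length, so these levels decide nothing. Induction by YAP was not tested and stays open.

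The difference between the MYC and the 4-week YAP effect was tested directly and passed for 1344 genes, among them Rprl3 (log2 difference 10.1), whose counts nearly vanished from the 5 YAP-induced libraries. Reads may have moved between near-identical RNase P RNA copies: against YAP controls Rprl2 fell and Rpph1 rose. The copies' summed CPM rose by 0.74 (log2, SD 0.25), which cannot decide, as totals can vary. An inherited difference between the mice is a further candidate: 9 genes were on in all libraries of one side and off in all of the other, reached by 1 of 792 splits, the real one, with 5 as the highest of the others. YAP induction can give such genes as well, so this count does not decide. Age, genotype and doxycycline history differ between the models and stay open, untested.

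Both YAP controls had a male pattern and all 3 4-week libraries a female one. Sex as the whole cause of the changes is argued against: over 3130 genes called at 4 weeks against control replicate 1, the male-pattern 2-week library had a median signed log2 change of 1.28 against control replicate 2, and 96.7% kept their direction. Sex as the whole cause of the fall of male-biased genes is argued against by their median of -4.46 in that library. There 17 of 17 were below both controls. The female-pattern 2-week library had larger shifts (1.61 and -7.26). Total-count scaling kept 31.8% of the lower and 100% of the higher calls at 4 weeks, and it shifts all genes upward by 0.73, so the choice of scaling stays open for the lower calls. How much sex adds at 4 weeks stays open.

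Further large log2 differences between the MYC and the 4-week YAP effect were 11.52 for Cyp4a12b, 11.34 for Tff3, 11.09 for Gata1, 10.39 for Rian, -11.49 for Zfp185, -11.49 for Cfap44, -11.17 for Fgf21, -10.04 for Sdk1 and -9.19 for H2-Q1; fitted values of genes without counts in a group depend on the prior count. Calls were lost for Gata1 (adjusted p = 1 without YAP control replicate 1 and 0.0516 without MYC control replicate 2), Cfap44 (adjusted p = 0.245 without MYC control replicate 2) and H2-Q1 (adjusted p = 0.0711 and 0.063 without YAP control replicates 1 and 2). Median log2 differences of lists were -2.58 for YAP/TAZ targets, -2.6 for cholangiocyte and progenitor markers, 1.74 for acute phase proteins, -1.12 for p53 targets, 1.09 for the unfolded protein response, 1.03 for oxidative phosphorylation and 0.41 for mitochondrial translation.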

How the results depend on the processing

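Total-count scaling, the sex term and leaving out listed muscle genes were chosen after seeing the data, the others before. With RLE size factors all 7 gene counts and overlaps stayed within 1.5 times, and all 200 list results kept direction and side of the threshold. With a filter of at least 1 CPM in at least 2 libraries the 7 counts stayed within 1.5 times too, and 2 list calls were lost. DESeq2 gave 77 genes for 4 against 2 weeks of YAP and 2350 for the difference between the MYC and YAP effects, and 5 counts stayed within 1.5 times. For 4 against 2 weeks, no filter gave 42 genes, a fit of the YAP model alone 0 (edgeR, against 11), total-count scaling 3 and leaving out the listed muscle genes 5, which removes 6 of the 11 by construction and leaves 4 muscle genes outside the list. Replicate numbers as blocks gave 3539 genes for 4 weeks of YAP, 1514 for MYC, 2 for 4 against 2 weeks, 308 for the difference and 732 for the overlap of MYC with 4-week YAP, which rose to 2630 with total-count scaling. The sex term, which in the YAP model rests on the 2-week libraries, gave 2565 genes at 2 weeks, 240 at 4 weeks, 0 for 4 against 2 weeks, 65 for the difference, 117 for the overlap of MYC with 4-week YAP and 237 for that of the YAP times. Leaving out 1 library at a time gave 2445 to 3671 genes at 2 weeks, 3324 to 6231 at 4 weeks, 792 to 4192 for MYC, 1 to 501 for 4 against 2 weeks and 338 to 1868 for the difference. The overlaps ran from 460 to 2175 for MYC with 4-week YAP and from 2207 to 4264 for the YAP times. Apart from the removal of listed muscle genes, the cause was not tested.

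The log2 fold change of Yap1 at 4 weeks turned to 0.54 with total-count scaling (adjusted p = 0.0338, range over alternatives 0.0338 to 0.676). With the sex term, the direction turned for erythroid markers at 4 weeks (adjusted p = 0.00114, range 0.00114 to 0.976) and, for 4 against 2 weeks, for the urea cycle (0.268, range 2.69e-07 to 0.837), male-biased genes (0.996, range 5.94e-12 to 0.996) and neutrophil markers (0.000179, range 7.67e-08 to 0.903). It also turned for the urea cycle in the difference between effects (0.981, range 3.35e-05 to 0.981). Without 2-week YAP replicate 1 the urea cycle (0.318) and neutrophil markers (0.000306, leave-one-out range 7.67e-08 to 0.845) turned for 4 against 2 weeks, and without 4-week YAP replicate 1 stellate markers did (0.0262, leave-one-out range 0.000829 to 0.582, all 0.000829 to 0.963). The sex term ended 18 list calls, added 12 and ended 39 of 123 calls of named examples. Total-count scaling ended 9 calls of named examples and added 2. An estimated correlation ended all 112 list calls and fry ended 38. Leaving out 1 library turned 3 list results, ended 46, added 50 and left 1061 as they were. Of calls among all genes named by the rule, 226 of 586 were lost without 1 library, against 30 of 123 among the examples printed, which were picked with that result in view. The cause was not tested. With 2 or 3 livers per group, changes near 2-fold were mostly below detection in simulated data with few changed genes. Where many more genes changed, as against controls, that rate does not carry over.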

Other observations

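These gene families were chosen after their values were seen, and each adjusted p with an estimated correlation was above 0.05. Replication-dependent histone genes rose with MYC, where 48 of 57 passed with a median log2 fold change of 3.62 (camera adjusted p = 6.81e-21, adjusted p = 0.235 with an estimated correlation). With YAP 16 rose and 1 fell at 2 weeks, and 10 rose and 1 fell at 4 weeks. By total counts 29, 28 and 49 rose at 2 and 4 weeks and with MYC. The MYC effect exceeded the 4-week YAP effect by a median of 1.58 (adjusted p = 3.93e-07, or 0.37 with an estimated correlation). By total counts the median was 1.29, and the 2 of 57 differing singly became 0 in edgeR. Interferon-stimulated genes were higher in all 3 comparisons with controls, with 12 of 26 genes that rose at 2 weeks of YAP, 11 at 4 weeks and 16 with MYC, 1 that fell at each YAP time, and medians of 1.44, 1.57 and 1.85. With total-count scaling 17, 20 and 19 rose.

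Of 13 mitochondrially encoded mRNAs, 4 fell at 2 weeks of YAP, or 2 by total counts. At 4 weeks 12 fell (median log2 fold change -1.81, or -1.1 by total counts). With MYC 0 of 13 passed in edgeR or DESeq2, and 0 had an unadjusted p under 0.05 in edgeR. Of 35 collagen genes 10 rose and 2 fell at 2 weeks of YAP (0 fell by total counts). At 4 weeks 13 rose and 3 fell. With MYC 7 fell, or 4 by total counts (medians -0.59 and -0.18). Of 83 cytosolic ribosomal protein genes 21 rose and 62 did not pass with MYC, 4 rose and 2 fell at 2 weeks of YAP, and 1 rose and 3 fell at 4 weeks. By total counts 58, 68 and 60 rose and 0 fell at 2 and 4 weeks and with MYC. Major urinary protein genes fell in all 3 comparisons with controls, 19, 20 and 20 of 21, a family whose reads cannot be assigned with certainty.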
